A study of Mus musculus with 12 samples.

How the data were processed

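RNA from mouse granulosa cells, the cells that line the ovarian follicle and surround the oocyte, was measured on 12 Affymetrix mouse genome expression arrays. Per the labels, each array carried RNA of cells pooled from 5 mice, and the cells were freed by puncturing single follicles. The treatment text speaks of 5 mice per group and does not state whether the 3 arrays of a group came from separate pools, so the spread between arrays may hold technical error alone. The mice were wild type (WT) or carried a deletion of exon 6 of Snf2l (Ex6DEL). Snf2l is the gene Smarca1, an ATPase of the ISWI chromatin remodellers. Females of 24 to 26 days of age received 5 IU of pregnant mare serum gonadotropin (PMSG), which drives follicle growth, and 48 h later the 0 h groups were collected. The other groups then received 5 IU of human chorionic gonadotropin (hCG), which acts through the luteinizing hormone (LH) receptor and starts ovulation, and were collected 4 h later.

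The deposited values are log2 intensities per probe set. GCRMA (version not given), named in the submitters' processing notes, corrects background, normalizes between arrays and summarises the probes of a set. The deposited table held 45101 probe sets on each array. All values lay between a floor of 2.21 and 18.2, and the array medians lay between 2.75 and 2.91. Between 36.4% and 40.5% of the probe sets of an array lay within 0.1 of the floor, where a change cannot be told from background. Among the genes tested the share was 28.1%. The number of arrays, 3 per group, limits the precision.

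A reference table paired 34958 probe sets with exactly 1 gene symbol. The 932 probe sets with several symbols and the 9211 that were not listed stayed outside the tests. A gene with several probe sets, as 9012 genes had, was represented by the probe set with the highest mean over the 12 arrays, which left 18194 genes. Neither a genome build nor probe positions were used here, so genes are given by symbol alone.

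One linear model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) to all 12 arrays in 4 groups of 3, without covariates, leaving 8 residual degrees of freedom. The estimated prior degrees of freedom were 0.626, so a gene's error rested almost wholly on its own values. The contrasts were WT 4 h minus 0 h, Ex6DEL 4 h minus 0 h, Ex6DEL minus WT at 0 h, Ex6DEL minus WT at 4 h, and the difference between the hCG responses of the genotypes (interaction). The moderated test of limma was two-sided, p-values were adjusted over all genes by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Genes called with at least a 2-fold change were counted as well. Errors of log2 changes are standard errors (SE) of the model, and intervals are at 95%.

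The tests, the alternatives, the rule for named genes and 19 gene lists were fixed before the data were examined. The lists cover LH-induced ovulatory genes, cumulus expansion matrix, steroid hormone synthesis, cholesterol synthesis and uptake, preovulatory granulosa genes, cell cycle, immediate early and MAPK feedback genes, cytokines and innate immune response, fibrinogen-like and coagulation genes, ISWI remodeller subunits, hypoxia response, luteal genes and heat shock genes. They also cover markers of oocytes, theca and stroma, endothelium, leukocytes, red blood cells and ovarian surface epithelium. Of their 322 symbols 297 were measured, and some stand in more than 1 list. Each list was tested with camera of limma at a preset correlation of 0.01, two-sided, adjusted over the 19 lists within a contrast, and again with the correlation estimated from the data. The count of members called over all genes is given beside the count adjusted over the list alone.

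Named genes are Smarca1 and Fgl2 (the gene of the series title) in every group. For each contrast they are also the 10 genes with the largest positive and the 10 with the largest negative log2 change among those called whose arrays did not overlap between groups (for the interaction, among those called), or all if fewer than 20 passed. If no gene passed, the 5 with the smallest p in each direction are given. Up to 4 members of each list with the smallest p are named too. Predicted genes are counted and not named. Any other gene is said to have been chosen after its values were seen.

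The alternatives were quantile normalization between arrays, a shift of all arrays to one median, genes above the median level of 4.74 only, values below the table median raised to it, the mean of all probe sets of a gene, every probe set tested by itself, eBayes with trend and robust, array weights, a fit of only the groups compared, the replicate number as a block, an adjusted p under 0.01, and each array left out in turn. For the lists they were fry and the estimated correlation. After the data had been seen, a fit without WT 0 h replicate 1 and Ex6DEL 0 h replicate 3, which both carried raised ovulatory genes, was added, and the same with genes above the median level only. Replicate numbers recur in all groups, and the labels do not say that a number marks a shared day or litter. In Ex6DEL the deviations of same-numbered arrays of 0 h and 4 h from their group means correlated at 0.143, 0.405 and 0.242, and each of these 6 arrays correlated best with its own number, so the Ex6DEL response is also given with the number as a block. Every alternative value comes from the same model with 1 choice changed, unless 2 choices are named.

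The procedure was tested on simulated data with the measured spread, in which 200 genes above the median level were changed. The recovery therefore does not cover dimmer genes. A log2 change of 1 was recovered in 5% of these genes for the WT response and 3% for the interaction. A log2 change of 2 was recovered in 50.5% for the WT response, 50% for the genotype difference at 4 h and 9% for the interaction, and a log2 change of 4 in 92.5%, 89% and 74%. For the WT response 5 of the 15 genes called at a log2 change of 1, 10 of 111 at 2 and 18 of 203 at 4 had not been changed, more than the 5% that the threshold aims at. A list shifted on purpose was called, and none of the 12 lists that shared no gene with it was. Each gene was drawn independently, so this does not test false calls of lists whose members vary together. The plots were drawn with Python 3.11.15 and matplotlib 3.10.9.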

Results

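Gene expression in granulosa cells was profiled before (0 h) and 4 h after an ovulatory dose of hCG in WT mice and in mice lacking exon 6 of Snf2l, with 3 arrays in each of the 4 groups. The series title gives the questions: the part of the ISWI ATPase Snf2l in superovulation, and its relation to Fgl2 in granulosa cells. The first principal component held 55.0% of the variance. It ran from 6.67 to 84.3 in the arrays of 0 h and from -67.0 to -18.6 in those of 4 h, and the value of 6.67 belonged to Ex6DEL 0 h replicate 3. Across genes, which are not independent replicates, that array correlated with the other arrays of its group at 0.866 to 0.927 and with single 4 h arrays at up to 0.954.

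Smarca1, the gene that lacks exon 6 in Ex6DEL, and Fgl2, a fibrinogen-like protein with prothrombinase activity, were examined first. Smarca1 had a log2 value of 10.72 ± 0.40 in WT and 10.76 ± 0.18 in Ex6DEL cells at 0 h (mean ± SD, n = 3 arrays). At 4 h the values were 11.36 ± 0.84 and 11.32 ± 0.77. Its difference between genotypes was 0.04 at 0 h (interval -1.05 to 1.13) and -0.04 at 4 h (interval -1.13 to 1.05), with a limma adjusted p of 1 at both times. Its change after hCG was 0.64 in WT (adjusted p = 0.589) and 0.56 in Ex6DEL (adjusted p = 0.568), and the interaction was -0.08 (SE 0.68). Replicate 1 carried these changes, at 12.32 in WT 4 h and 12.19 in Ex6DEL 4 h against 10.72 to 11.05 in the other arrays of 4 h. Without WT 4 h replicate 1 the Smarca1 change in WT was 0.16, and without Ex6DEL 4 h replicate 1 that in Ex6DEL was 0.13. The array has 1 Smarca1 probe set whose place relative to exon 6 was not examined here, so these values do not check the genotype. Fgl2 had a log2 value of 3.71 ± 0.95 in WT at 0 h and 6.92 ± 2.27 at 4 h (SD, n = 3 arrays). In Ex6DEL it had 4.98 ± 2.56 and 6.54 ± 1.21. Its log2 change after hCG was 3.22 in WT (SE 1.48, adjusted p = 0.370) and 1.56 in Ex6DEL (SE 1.48, adjusted p = 0.612), neither past the threshold. The Fgl2 difference between genotypes was 1.27 at 0 h (adjusted p = 0.968) and -0.38 at 4 h (interval -3.74 to 2.98, adjusted p = 1). Its interaction was -1.66 (SE 2.09, adjusted p = 0.878). The other Fgl2 probe set changed by 2.05 in WT and 0.48 in Ex6DEL. Its genotype difference was 0.47 at 0 h and -1.10 at 4 h, and its interaction -1.57. Replicate 1 had the highest Fgl2 value in each of the 4 groups. It had 4.81 against 3.16 and 3.15 in WT 0 h, 9.41 against 4.96 and 6.40 in WT 4 h, 7.92 against 3.20 and 3.82 in Ex6DEL 0 h, and 7.93 against 5.86 and 5.83 in Ex6DEL 4 h. Without Ex6DEL 0 h replicate 1 the Fgl2 difference at 0 h turned to -0.20, and without WT 4 h replicate 1 that at 4 h turned to 0.86. Without WT 4 h replicate 1 the Fgl2 change in WT was 1.98. That in Ex6DEL ranged from 0.67 without Ex6DEL 0 h replicate 2 to 3.03 without Ex6DEL 0 h replicate 1. The sign of the Smarca1 differences turned under quantile normalization, to -0.47 at 0 h and 0.14 at 4 h.

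**Figure D1:**
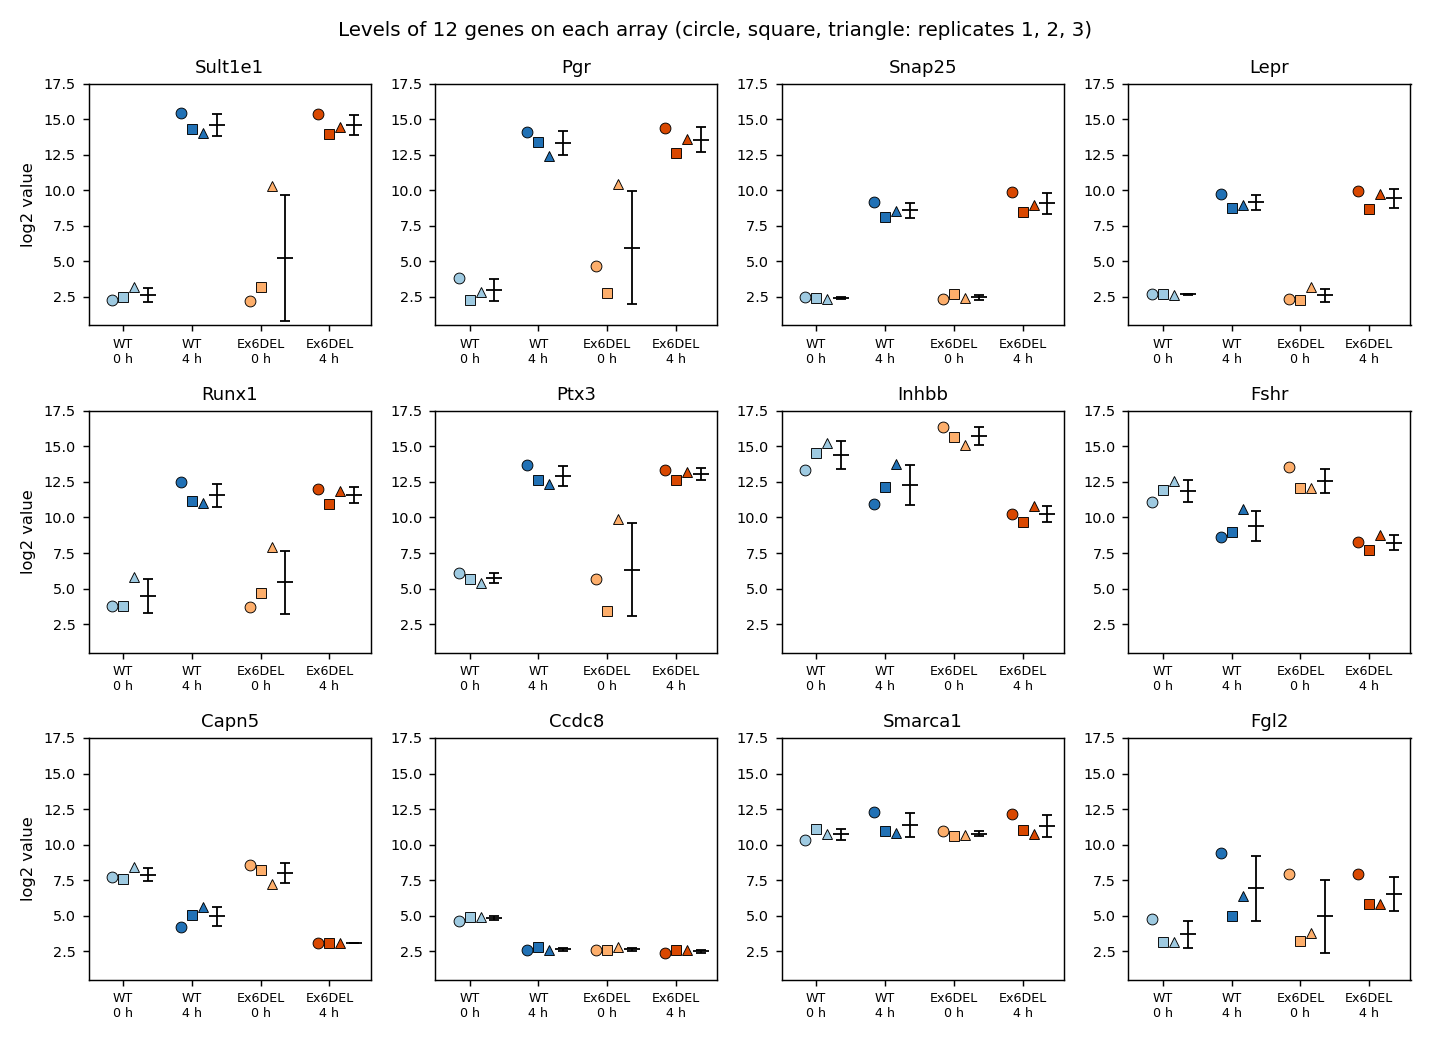
Log2 values of 12 genes (vertical axes) on each array of the 4 groups (horizontal axes), with the mean and SD of 3 arrays as a bar beside the points. Snap25 and Lepr lie near the floor of 2.21 in all arrays of 0 h and above 8 in all of 4 h, while Sult1e1 and Pgr lie above 10 in Ex6DEL 0 h replicate 3.

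The WT arrays of 4 h against 0 h give the response of normal granulosa cells to the ovulatory signal. Sult1e1, the estrogen sulfotransferase, rose by 11.92 on the log2 scale (SE 1.79, n = 3 arrays per group, adjusted p = 0.0289), from 2.66 ± 0.48 to 14.58 ± 0.76 (SD). Btc, a ligand of the EGF receptor, rose by 11.27 (SE 1.96), Nts, the precursor of neurotensin, by 11.23 (SE 1.62), and Pgr, the progesterone receptor, by 10.31 (SE 1.66). The leptin receptor Lepr rose by 6.46 (SE 0.38, adjusted p = 3.16e-04) and the vesicle fusion protein gene Snap25 by 6.15 (SE 0.36, adjusted p = 3.16e-04). Msc, a helix-loop-helix repressor, rose by 7.75, the transcription factor gene Runx1 by 7.09, Tac1, the precursor of substance P, by 6.69, and the interferon-inducible Ifi202b by 6.55. The largest decreases were smaller. Cyfip2, whose protein is part of the actin-regulating WAVE complex, changed by -3.12 (SE 0.57, adjusted p = 0.0481), Mapk1ip1 by -2.94, the calpain gene Capn5 by -2.94 and Dpf3, a subunit of BAF chromatin remodellers, by -2.93. P2ry6, a receptor for UDP, changed by -2.32, Ccdc8 by -2.18, the exocyst subunit gene Exoc6 by -2.13, Aldh1a7 by -2.09, the histone acetyltransferase gene Kat6b by -2.05 and Cep57l1 by -2.02. The 0 h means of Sult1e1 (2.66), Lepr (2.69) and Snap25 (2.45) and the 4 h means of Dpf3 (2.55) and Ccdc8 (2.64) lay below the lowest array median of 2.75, so the size of these changes rests on values near background. In all, limma called 169 of 18194 genes, 111 up and 58 down, of which 148 changed at least 2-fold. The arrays did not overlap between 0 h and 4 h for 18.9% of all genes. Chance gives 10% for genes without tied values and less for genes with ties, such as those at the floor.

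The call of most of these genes rested on the spread of all 12 arrays. Only Lepr, Snap25 and Ccdc8 of the 26 named genes called in WT passed in each of the 12 fits without one array. The predominance of increases did not hold when any WT array of 0 h was left out. The split was 58 up and 140 down without WT 0 h replicate 1, 25 and 28 without replicate 2, and 46 and 65 without replicate 3. With array weights 774 were up and 1515 down, and without Ex6DEL 0 h replicate 1 the split was 170 and 174. The count was 53 and 50 without WT 4 h replicates 1 and 2, 271 without Ex6DEL 0 h replicate 3, and 80, 81 and 56 without Ex6DEL 4 h replicates 1, 2 and 3. It was 135 up and 185 down without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3. After a shift of all arrays to one median 300 were up and 69 down (81.3% up against 65.7%), and this moved the median change of genes above the median level by 0.22.

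Ovulatory gene groups were higher at 4 h in WT cells. Of the 28 measured LH-induced ovulatory genes 6 rose, 13 adjusted over the list alone, and 22 did not pass (camera adjusted p = 3.10e-16, adjusted p = 0.125 with an estimated correlation). All 28 had a positive change. The error of each gene held the spread of all 4 groups, and Ex6DEL 0 h replicate 3 stood high in this list, at a mean of 9.22. The members that did not pass are therefore not shown to be unchanged in WT. Of the 14 genes of the cumulus expansion matrix, the hyaluronan-rich coat laid down around the oocyte, 3 rose and 9 did so adjusted over the list alone. Camera gave an adjusted p = 3.32e-11 for this list, and adjusted p = 0.0415 with an estimated correlation. The risen genes were the matrix proteases Adamts4 (3.68) and Adamts9 (2.30) and the protease inhibitor Timp1 (3.01), while the pentraxin gene Ptx3 (7.16) had an adjusted p of 0.0522. Among 15 steroid synthesis genes Sult1e1 and the HDL receptor Scarb1 (1.75) rose, 3 adjusted over the list alone with the ferredoxin gene Fdx1 (2.05, adjusted p = 0.135 over all genes). Among 13 luteal genes 1 rose, again Scarb1, and 5 did so adjusted over the list alone. Of 17 coagulation genes the urokinase gene Plau (4.69) and the protein C receptor gene Procr (4.86) rose, 2 adjusted over the list alone, while tissue factor, F3, had a change of 7.12 with an SE of 2.62. The camera adjusted p was 0.00495 for steroid synthesis, 2.55e-04 for luteal genes and 1.61e-04 for coagulation genes, and each had an adjusted p = 0.125 with an estimated correlation. After quantile normalization the steroid and luteal calls were lost (adjusted p = 0.423 and 0.0755).

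No single member passed over all genes in the other groups that camera called in WT. The 27 immediate early and MAPK feedback genes were higher as a list (camera adjusted p = 5.38e-09, adjusted p = 0.253 with an estimated correlation), and 5 passed adjusted over the list alone, among them Ier3 (5.50), the MAPK inhibitor gene Spry2 (3.32) and the MAPK phosphatase gene Dusp4 (2.88). This list also stood high in WT 0 h replicate 1, at a mean of 8.0 against 6.17 and 6.36 in the other WT arrays of 0 h. The 15 cholesterol genes were higher (camera adjusted p = 0.00103, adjusted p = 0.353 with an estimated correlation), with Cyp51 at 2.27 as the 1 member passing over the list alone. The 19 hypoxia genes were higher (camera adjusted p = 0.00408, adjusted p = 0.125 with an estimated correlation). Over the list alone 3 rose, among them the glucose transporter gene Slc2a1 (2.67), and 1 fell, Bnip3 (-2.02). The 11 heat shock genes (camera adjusted p = 0.00874, adjusted p = 0.294 with an estimated correlation) had 1 member passing over the list alone, Hsph1 at 2.38, and Hspa1a had a change of -1.66. The 21 cytokine genes (camera adjusted p = 0.0342, adjusted p = 0.125 with an estimated correlation) had 1, the interleukin receptor gene Il1r1 at 2.64. The 29 cell cycle genes were lower as a list (camera adjusted p = 0.00123, adjusted p = 0.490 with an estimated correlation), such as Kif11 (-0.90) and Aurkb (-1.39) but with Pcna at 1.45. So were the 23 preovulatory granulosa genes (camera adjusted p = 0.0342, adjusted p = 0.512 with an estimated correlation), such as the FSH receptor gene Fshr (-2.44). After quantile normalization the calls of cholesterol (adjusted p = 0.0755), hypoxia and cytokine genes (adjusted p = 0.0947 each) and heat shock genes (adjusted p = 0.165) were lost. With genes above the median level only, the preovulatory and cytokine calls were lost (adjusted p = 0.0819 and 0.0812). Without WT 0 h replicate 3 the cell cycle, preovulatory and cytokine calls were lost (adjusted p = 0.199, 0.288 and 0.199). Heat shock genes and cytokines were lost without WT 4 h replicate 1 (adjusted p = 0.0705 and 0.0818). The same held for preovulatory genes without WT 4 h replicate 2 (adjusted p = 0.0563) and cytokines without Ex6DEL 0 h replicate 1 (adjusted p = 0.0532). Lists of other cell types were not called between 0 h and 4 h in WT. Oocyte markers had an adjusted p of 0.0771, red blood cell markers 0.160, leukocyte markers 0.309, surface epithelium 0.480, endothelium 0.631 and theca and stroma 0.969. The ISWI subunits had 0.200. Oocyte markers passed as higher without WT 0 h replicate 3 (adjusted p = 0.00166) and red blood cell markers without WT 4 h replicate 1 (adjusted p = 0.0467).

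The same comparison in Ex6DEL cells asks how granulosa cells with the deletion respond to hCG. Sult1e1 rose by 9.35 (SE 1.79, n = 3 arrays per group, adjusted p = 0.0422), Nts by 8.48 (SE 1.62), Lepr by 6.83 (SE 0.38, adjusted p = 3.93e-04). Msc rose by 6.77, the cumulus matrix gene Ptx3 by 6.73 and Snap25 by 6.60 (SE 0.36, adjusted p = 3.93e-04). Prkg2, a cGMP-dependent kinase, rose by 6.15 (SE 0.49, adjusted p = 0.00307), Runx1 by 6.15, Ifi202b by 5.79 and Nmu, the precursor of neuromedin U, by 5.78. Lepr and Snap25 had 0 h means of 2.61 and 2.49, below the median of every array, and Capn5 had 3.11, 3.08 and 3.08 in the Ex6DEL arrays of 4 h, so the size of these changes rests on values near background. Sult1e1 had 2.24 and 3.20 in Ex6DEL 0 h replicates 1 and 2, which limits the size of its change too. Inhbb, the beta B subunit of inhibin and activin, changed by -5.45 (SE 0.76, adjusted p = 0.0269), Fshr by -4.34 (SE 0.64, adjusted p = 0.0285) and Capn5 by -4.90 (SE 0.43, adjusted p = 0.00479). The other Inhbb probe set changed by -3.37. Smim10l2a changed by -5.60, the proton-activated chloride channel gene Pacc1 by -5.53, the centrosomal gene Alms1 by -5.43, Tmem25 by -5.33, the aldo-keto reductase gene Akr1c13 by -5.06, Cables1 by -4.42 and Insyn2b by -4.35. Limma called 394 genes, 103 up and 291 down, of which 376 changed at least 2-fold. The arrays of 0 h and 4 h did not overlap for 19.7% of all genes, where chance gives 10% without ties and less with them. After quantile normalization, which moved the median change of genes above the median level by 0.33 from -0.34, 206 genes were up and 235 down (46.7% up against 26.1%). After a shift to one median, which moved it by 0.20, 213 were up and 325 down (39.6% up). With the replicate number as a block limma called 92 genes, 33 up and 59 down.

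One array weighed on this response. In Ex6DEL 0 h replicate 3 the LH-induced ovulatory genes had a mean of 9.22 against 6.22 and 6.04 in the other Ex6DEL arrays of 0 h. The immediate early genes had 10.23 against 6.18 and 6.54. Without it 1256 genes were called, 288 up and 968 down. The change of Sult1e1 was 11.87, of Nts 10.81 and of Ptx3 8.51. Without it and WT 0 h replicate 1 the split was 278 up and 1015 down. The count was 95 and 255 without WT 4 h replicates 2 and 3, and 32 and 240 without WT 0 h replicates 2 and 3. It was 53 and 34 without Ex6DEL 0 h replicates 1 and 2, and 151 without Ex6DEL 4 h replicate 2. The predominance of decreases turned without Ex6DEL 4 h replicate 1, to 67 up and 50 down, and without replicate 3, to 18 up and 8 down. Only Lepr, Snap25, Prkg2 and Capn5 of the 29 named genes called passed in each of the 12 fits without one array. Sult1e1, Nts and Ptx3 passed in 1 of these fits.

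The LH-induced ovulatory genes were higher at 4 h in Ex6DEL too, with 4 of 28 rising, Snap25, Runx1, Sult1e1 and Ptx3, and 11 adjusted over the list alone (camera adjusted p = 5.74e-11, adjusted p = 0.180 with an estimated correlation). Btc and Pgr, called in WT, did not pass here, though they changed by 8.85 and 7.57. In Ex6DEL 0 h replicate 3 they stood at 10.99 and 10.44. Other probe sets changed in Ex6DEL by 5.96 for Btc and by 4.11 and 0.38 for Pgr. Of the cumulus matrix genes 4 of 14 rose, Adamts4 by 3.90, Timp1 by 2.88, Adamts9 by 1.94 and Ptx3. Adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 1.21e-07, adjusted p = 0.0682 with an estimated correlation). The preovulatory granulosa genes were lower, with 7 of 23 falling and 15 adjusted over the list alone (camera adjusted p = 7.43e-10, adjusted p = 0.153 with an estimated correlation). Besides Fshr and Inhbb these included Mro (-3.09, SE 0.37) and the estrogen-regulated gene Greb1 (-3.07, SE 0.51). After quantile normalization that list still had a mean change of -1.62 and the same direction of call. Cell cycle genes were lower as a list (camera adjusted p = 8.85e-05, adjusted p = 0.521 with an estimated correlation), with no member past the threshold over all genes. Adjusted over the list alone 10 of 29 fell, such as Aurkb (-1.98) and the cyclin genes Ccnb2 (-3.24) and Ccna2 (-0.63). Theca and stroma markers were lower as well, with no member past the threshold (camera adjusted p = 0.00421, adjusted p = 0.521 with an estimated correlation). Tcf21 had a change of -2.95 and the collagen gene Col3a1 of -2.10, and that list's call was lost without Ex6DEL 0 h replicate 1 (adjusted p = 0.157). In this array the theca and stroma markers had a mean of 10.12 against 7.82 and 7.09 in the other Ex6DEL arrays of 0 h, and the preovulatory genes 12.51 against 11.66 and 11.47.

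Cytokine genes were higher in Ex6DEL at 4 h, with 2 of 21 rising adjusted over the list alone, Il1r1 (2.45) and the cytokine signalling inhibitor Socs3 (1.28). This call held with an estimated correlation (camera adjusted p = 1.66e-04, adjusted p = 0.0417 with an estimated correlation). Immediate early genes were higher (camera adjusted p = 8.08e-05, adjusted p = 0.521 with an estimated correlation) without a member passing over the list alone, Egr3 having a change of 5.74 with an SE of 1.60. Of the coagulation genes Plau rose by 4.04, and 3 of 17 rose adjusted over the list alone (camera adjusted p = 6.05e-04, adjusted p = 0.180 with an estimated correlation). In the other lists Sult1e1 rose and Hsd17b1, which makes estradiol, fell (-2.88) among the steroid genes. Parm1 rose (1.84) among the luteal genes and Bnip3 fell (-3.02) among the hypoxia genes. As lists these had camera adjusted p of 0.624, 0.0529 and 0.261. Adjusted over the list alone 1 steroid gene rose and 2 fell, 2 luteal genes rose and 2 fell, and 1 hypoxia gene fell. Camera gave 0.0603 for cholesterol genes, 0.890 for heat shock genes, 0.973 for ISWI subunits, 0.0529 for surface epithelium, 0.0914 for leukocytes, 0.299 for oocytes, 0.671 for endothelium and 0.671 for red blood cells. With the replicate number as a block the cholesterol and surface epithelium lists passed as higher (adjusted p = 0.0462 and 0.0432). Cholesterol genes also passed after quantile normalization (adjusted p = 0.0273) and above the median level (adjusted p = 0.0238). Luteal genes passed above the median level (adjusted p = 0.0334) and without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3 (adjusted p = 0.0308). With 1 array left out 5 of the 11 lists not called passed in at least 1 fit, each with its lowest adjusted p without Ex6DEL 4 h replicate 3. These were surface epithelium (0.00912), cholesterol (0.00385), luteal genes (0.0105) and leukocytes (0.00798) as higher and oocyte markers (0.0120) as lower. For the ISWI subunits the median change of -0.34 and the mean of -0.13 stood against an upward direction in camera. Over all contrasts the median, mean and camera direction differed in sign in 17 of the 60 list tests that were not called, and in none of the 35 that were.

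**Figure D2:**
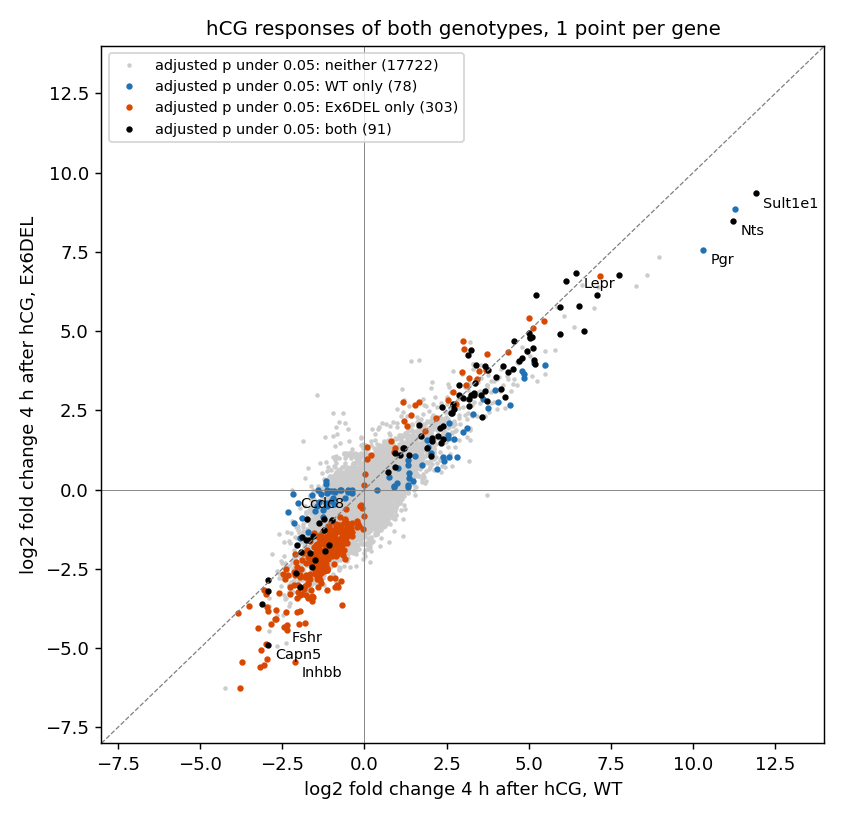
Log2 change 4 h after hCG in WT (horizontal axis) and Ex6DEL (vertical axis), with 1 point per gene coloured by the test it passed and the dashed line marking equal changes. The 91 genes called in both genotypes lie in the upper right and lower left.

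The changes after hCG in the 2 genotypes correlated at r = 0.805 across all genes and at 0.854 across genes above the median level. Genes are not independent replicates, so no p is given. Of the 169 genes called in WT, 91 were called in Ex6DEL with the same sign, 69 up and 22 down, where lists drawn independently would share 0.628 and 0.928. Both responses were tested against the same error of a gene, which favours genes with a small error in both lists. The shared count is therefore raised over that of independent lists by the fit itself. Counting genes that did not pass in Ex6DEL, 163 of the 169 (96.4%) had the same sign there, and 393 of the 394 genes called in Ex6DEL had it in WT. The median ratio of the Ex6DEL to the WT change over the WT calls was 0.760, and that of the WT to the Ex6DEL change over the Ex6DEL calls was 0.673. Each ratio is lowered by picking genes for their change in its denominator, so neither shows a weaker response in 1 genotype.

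**Figure D3:**
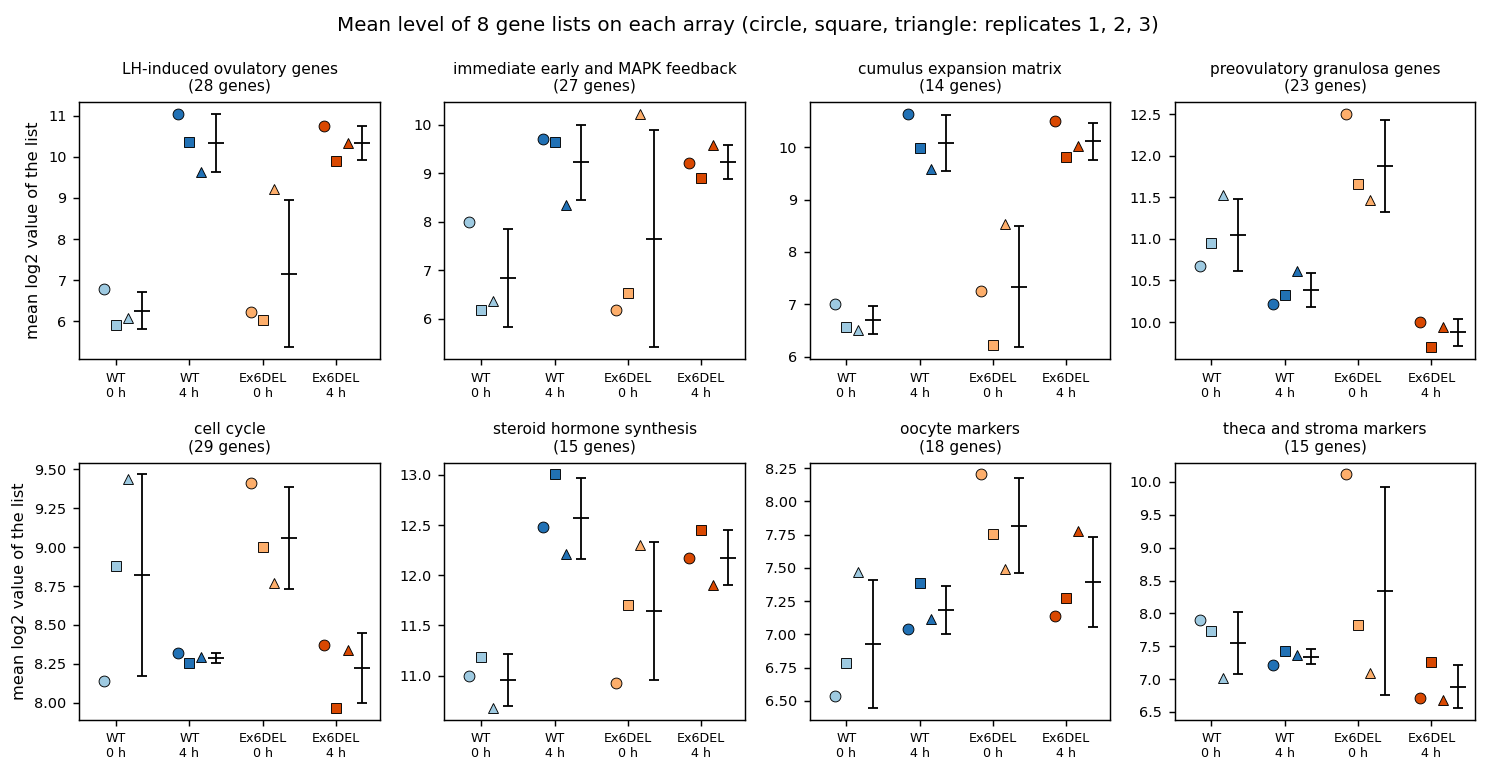
Mean log2 value of 8 gene lists (vertical axes) on each array of the 4 groups (horizontal axes), with the mean and SD of 3 arrays as a bar beside the points. The ovulatory list lies at 9.22 in Ex6DEL 0 h replicate 3 and the theca and stroma list at 10.12 in Ex6DEL 0 h replicate 1, each above the other 5 arrays of 0 h.

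The genotypes at 0 h show whether the deletion altered PMSG-primed granulosa cells before the ovulatory signal. Ccdc8 was lower in Ex6DEL by -2.18 (SE 0.10, n = 3 arrays per group, adjusted p = 1.02e-04), at a mean of 2.64 near background, and Fbxo17, an F-box protein gene, by -1.12 (SE 0.10, adjusted p = 0.00750). Minar2 was lower by -0.91 (SE 0.07, adjusted p = 0.00230), Abraxas1, a DNA damage response scaffold, by -0.92 (SE 0.10, adjusted p = 0.0271) and Hlcs, which attaches biotin to carboxylases, by -0.71 (SE 0.08, adjusted p = 0.0353). With 1 predicted gene these were the 6 genes limma called, all lower in Ex6DEL, with 975 genes at an unadjusted p under 0.05. All 6 were dim, with mean levels of 2.41 to 4.31. Outside WT 0 h Hlcs had the same value of 3.70 in all 9 arrays and Minar2 of 4.09 in 8 of them, so their small SE comes from arrays without spread and the differences are set against background. When only genes above the median level were tested limma called 0, with the same count of 0 when only the groups compared were fitted. The arrays of the genotypes did not overlap for 1166 genes, 6.41% of all. Chance gives 10% without ties and less with them, and that lower share was not computed. Without WT 0 h replicates 1, 2 and 3 the count was 49, 13 and 41, of which 1, 0 and 2 were higher in Ex6DEL. The calls went both ways without Ex6DEL 0 h replicates 1 (4 up, 5 down), 2 (6 up, 7 down) and 3 (17 up, 8 down). Without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3 there were 18 up and 43 down.

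Gene lists at 0 h differed between genotypes as lists, with no member past the threshold over all genes. Oocyte markers were higher in Ex6DEL (camera adjusted p = 6.95e-08, adjusted p = 0.334 with an estimated correlation), with 5 of 18 passing adjusted over the list alone. Among these were Nlrp14 (1.39), the oocyte growth factor gene Gdf9 (1.62), Nlrp5 (1.71) and Padi6 (1.63). Preovulatory granulosa genes were higher, with no member passing over the list alone (camera adjusted p = 5.94e-07, adjusted p = 0.334 with an estimated correlation). Mro had a difference of 1.36, the gap junction gene Gja1 of 1.20 and the inhibin alpha gene Inha of 0.94. After quantile normalization the mean difference of the list of 0.83 was 0.21 (adjusted p = 0.0557). Without Ex6DEL 0 h replicate 1, where this list stood highest, the mean difference was 0.52 (camera adjusted p = 1.69e-04). Heat shock genes such as Hspa8 (1.29) were higher (camera adjusted p = 0.0119, adjusted p = 0.373 with an estimated correlation). That call was lost without WT 0 h replicate 1 (adjusted p = 0.0555) or Ex6DEL 0 h replicate 3 (adjusted p = 0.144). The theca and stroma markers such as Col1a2 (1.78) were higher (camera adjusted p = 0.0164, adjusted p = 0.572 with an estimated correlation). Their mean of 0.80 was 0.53 without WT 0 h replicate 3 (adjusted p = 0.269) and -0.09 without Ex6DEL 0 h replicate 1 (adjusted p = 0.375). Ovulatory genes such as Rgs2 (1.47), immediate early genes such as Fosl2 (1.06) and steroid synthesis genes such as Hsd3b1 (1.12) each had a camera adjusted p of 0.0318 and an adjusted p = 0.572, 0.614 and 0.334 with an estimated correlation. Without Ex6DEL 0 h replicate 3 the mean of the ovulatory list went from 0.90 to -0.13 (adjusted p = 0.272). That of the immediate early list went from 0.81 to -0.48 (adjusted p = 0.0774) and that of the steroid list from 0.69 to 0.36 (adjusted p = 0.400). The ovulatory and immediate early calls were also lost without WT 0 h replicate 2 (adjusted p = 0.135 and 0.234) or 3 (adjusted p = 0.127 and 0.30). The steroid call was lost without WT 0 h replicate 3 (adjusted p = 0.137) or Ex6DEL 0 h replicate 2 (adjusted p = 0.112). Surface epithelium markers such as Epcam (-1.17) were lower (camera adjusted p = 0.00115, adjusted p = 0.334 with an estimated correlation). Their call was lost without WT 0 h replicate 1 (adjusted p = 0.0555) or Ex6DEL 0 h replicate 3 (adjusted p = 0.0774). With genes above the median level only, the ovulatory and theca calls (adjusted p = 0.0626 each), the immediate early and steroid calls (adjusted p = 0.0909 each) and the heat shock call (adjusted p = 0.0600) were lost. After quantile normalization the heat shock (adjusted p = 0.386) and steroid calls (adjusted p = 0.972) were lost. Without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3 the calls of ovulatory (adjusted p = 0.976), immediate early (0.901), steroid (0.539) and heat shock genes (0.581) and surface epithelium (0.697) were lost. In that fit the mean difference of the surface epithelium list turned from negative to positive. The remaining lists had camera adjusted p of 0.0958 for the cumulus matrix, with Lama1 (1.22) the 1 of 14 passing over the list alone, 0.116 for cytokines, 0.134 for coagulation, and 0.134 for ISWI subunits. They were 0.140 for hypoxia, 0.153 for luteal genes, 0.155 for cell cycle, 0.271 for red blood cells, 0.406 for cholesterol, 0.453 for leukocytes and 0.514 for endothelium. With 1 array left out 8 of these 11 lists passed in at least 1 fit. Without Ex6DEL 0 h replicate 1 these were luteal (adjusted p = 1.03e-04) and hypoxia genes (0.0410), and without Ex6DEL 0 h replicate 2 the cumulus matrix (0.00214) and coagulation genes (0.0232). Without WT 0 h replicate 2 they included cholesterol genes (0.0256), and without WT 0 h replicate 3 the cell cycle (5.15e-04) and ISWI subunits (0.0438) as higher and endothelium (0.0276) as lower.

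The genotypes at 4 h show whether granulosa cells differed after the ovulatory signal. No gene passed: limma called 0 of 18194 genes, with 294 at an unadjusted p under 0.05. The arrays of the genotypes did not overlap for 2.98% of genes. Chance gives 10% without ties and less with them, and that lower share was not computed. The genes with the smallest p, all with an adjusted p of 1, had higher values in Ex6DEL for Fbxw16 (0.97), Ppbp (0.14), Tbrg3 (0.91), the potassium channel gene Kcna1 (0.47) and the syntrophin gene Sntb2 (0.79). They had lower values for Epm2aip1 (-2.03, SE 0.33), Arid3b (-0.39), Elmo1 (-0.67), the neuregulin receptor gene Erbb4 (-0.10) and Bphl (-0.95). Ppbp in WT 4 h and Arid3b in Ex6DEL 4 h lay at the floor of 2.21 without spread and Erbb4 in Ex6DEL 4 h at 2.25, so these 3 differences are set against background. Tbrg3 had 3.91 without spread in both 0 h groups and 3.98 ± 0.09 (SD) in WT 4 h. Kcna1 had group means of 3.42 to 3.43 outside Ex6DEL 4 h. The differences of Tbrg3 and Kcna1 may thus be set against background too. Leaving out 1 array gave 9, 5 and 5 genes without WT 4 h replicates 1, 2 and 3, and 1 without WT 0 h replicate 1. It gave 35, 1 and 4 without Ex6DEL 4 h replicates 1, 2 and 3, and 3 genes passed when every probe set was tested.

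Among the lists at 4 h the preovulatory granulosa genes were lower in Ex6DEL (camera adjusted p = 7.02e-04, adjusted p = 0.871 with an estimated correlation). Inhbb had -2.01 (SE 0.76), Fshr -1.17 and Greb1 -0.91, and no member passed over all genes or over the list alone. The other Inhbb probe set had -0.47. Oocyte markers were higher, such as Kit (0.72) and Mos (0.91), again with no member past the threshold (camera adjusted p = 0.0133, adjusted p = 0.871 with an estimated correlation). The preovulatory call was lost without Ex6DEL 4 h replicate 2 (adjusted p = 0.0675). The oocyte call was lost without WT 4 h replicates 1 and 3 (adjusted p = 0.215 and 0.0623) and Ex6DEL 4 h replicate 3 (adjusted p = 0.740). The ovulatory list (mean difference -0.01, adjusted p = 0.736), the cumulus matrix (0.04, adjusted p = 0.736) and immediate early genes (0.00, adjusted p = 0.852) gave no call, with Edn2 at -0.78, Lama1 at 0.42 and Fosl1 at 0.67. Camera gave an adjusted p of 0.190 for steroid synthesis, 0.190 for theca and stroma, 0.267 for surface epithelium and 0.282 for coagulation, with the plasminogen activator inhibitor gene Serpinb2 at 2.43. It gave 0.282 for luteal genes and 0.381 each for cholesterol, cytokines, hypoxia and heat shock genes. It gave 0.609 for leukocytes, 0.736 for cell cycle and endothelium, and 0.941 for ISWI subunits and red blood cells. With genes above the median level only, leukocyte markers passed as higher in Ex6DEL (adjusted p = 0.00150). With 1 array left out 5 of the 17 lists not called passed in 1 fit each. Coagulation genes were higher without WT 4 h replicate 1 (adjusted p = 0.00603). Steroid (0.0349) and heat shock genes (0.0208) were lower without WT 4 h replicate 3, theca and stroma markers (0.00305) without Ex6DEL 0 h replicate 1 and cholesterol genes (0.00762) without Ex6DEL 4 h replicate 2.

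The interaction tests whether the hCG response itself differed between genotypes. Ccdc8 fell in WT and had a change of -0.13 in Ex6DEL, where it was near the floor at both times. The responses differed by 2.05 (SE 0.14, n = 3 arrays per group, adjusted p = 0.00322). With 1 predicted gene, Gm1976, named here after its values were seen, at 0.75, these were the 2 genes limma called. Gm1976 lay at 2.22 to 2.24 outside WT 0 h, at the floor, so both interactions come from the same 3 raised WT arrays as the differences at 0 h. There were 583 genes at an unadjusted p under 0.05. The number called was 8, 5 and 5 without WT 4 h replicates 1, 2 and 3, and 16, 6 and 17 without WT 0 h replicates 1, 2 and 3. It was 4, 5 and 13 without Ex6DEL 0 h replicates 1, 2 and 3, and 23 without Ex6DEL 4 h replicate 1. Limma called 0 when only genes above the median level were tested and 28 without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3.

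As lists, preovulatory granulosa genes had a more negative change after hCG in Ex6DEL than in WT, by a mean of -1.34 (camera adjusted p = 1.25e-08, adjusted p = 0.314 with an estimated correlation). No member passed the threshold, and Inhbb had -3.34 (SE 1.07), Greb1 -2.25, Mro -1.68 and Gja1 -1.59. The other Inhbb probe set had -0.88, with changes of -2.49 in WT and -3.37 in Ex6DEL. After quantile normalization the mean of the list was -0.59 and the list was still called. Theca and stroma markers such as Col1a2 (-2.46) had a mean of -1.26 (camera adjusted p = 0.00979, adjusted p = 0.708 with an estimated correlation). This call was lost without WT 0 h replicate 3 (adjusted p = 0.0813) and, at a mean of -0.37, without Ex6DEL 0 h replicate 1 (adjusted p = 0.253). Steroid synthesis genes such as Hsd17b1 (-2.17) had a mean of -1.09, heat shock genes such as Hspa8 (-1.74) of -0.79 and oocyte markers such as Gdf9 (-1.50) of -0.68. Each had a camera adjusted p of 0.0124 and an adjusted p = 0.314, 0.550 and 0.708 with an estimated correlation. After quantile normalization the steroid and heat shock calls were lost, at means of -0.33 and -0.11. Without Ex6DEL 0 h replicate 3 they were lost too (adjusted p = 0.157 and 0.128), as they were without Ex6DEL 4 h replicate 3 (adjusted p = 0.0641 and 0.0551). The same held without WT 4 h replicate 2 (0.0865, steroid) or 1 (0.138, heat shock). The oocyte call was lost without WT 4 h replicate 2 (adjusted p = 0.0560), WT 0 h replicate 2 (0.0703) and Ex6DEL 4 h replicates 1 and 2 (0.159 and 0.0856). Without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3 the steroid, heat shock and oocyte calls were lost (adjusted p = 0.195, 0.339 and 0.0743). No other list was called. With genes above the median level only, cytokines (adjusted p = 0.0461), leukocytes (0.00391) and surface epithelium (0.0417) passed as well. On all genes the adjusted p was 0.197 for ovulatory genes, 0.222 for the cumulus matrix, 0.184 for immediate early genes, 0.0955 for cytokines, 0.0961 for luteal genes and 0.113 for hypoxia. It was 0.222 for cell cycle, 0.222 for cholesterol, 0.278 for ISWI subunits, 0.786 for coagulation, 0.182 for surface epithelium, 0.336 for leukocytes, 0.450 for red blood cells and 0.893 for endothelium. With 1 array left out 9 of these 14 lists passed in at least 1 fit. Without Ex6DEL 0 h replicate 1 the ovulatory (adjusted p = 0.00688), immediate early (3.38e-04) and luteal lists (1.70e-04) had a more negative change in Ex6DEL. So had hypoxia genes without WT 4 h replicate 3 (0.0226), cholesterol genes without Ex6DEL 4 h replicate 2 (0.0153), cell cycle genes without WT 0 h replicate 3 (0.00398) and the cumulus matrix without Ex6DEL 0 h replicate 2 (0.0219). Cytokines without Ex6DEL 4 h replicate 3 (0.0202) and surface epithelium without WT 0 h replicate 3 (0.0101) had a more positive one.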

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

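The tests of the 3 patterns weighed in this part were all chosen after the results had been seen, while the interaction tests were planned.

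The interaction test called 2 genes and 5 lists, and the splits of the arrays given below do not exclude chance for the 2 genes. The response of Ccdc8 differed by 2.05 and that of Gm1976 by 0.75 on the log2 scale, both through the 3 WT arrays of 0 h, since the 9 other arrays lay at 2.39 to 2.78 and 2.22 to 2.24, near the floor of 2.21. The mean difference between responses was -1.34 for preovulatory granulosa genes, -1.26 for theca and stroma markers, -1.09 for steroid hormone synthesis, -0.79 for heat shock genes and -0.68 for oocyte markers. With an estimated correlation none of these lists passed (adjusted p = 0.314, 0.708, 0.314, 0.550 and 0.708), nor did any with fry. Among the 10092 probe sets without a single gene symbol, array controls left out, which entered none of the comparisons, 11 passed for WT 4 h after hCG, 9 up and 2 down, and 6 passed for Ex6DEL, all up.

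In Ex6DEL 0 h replicate 3 ovulatory genes stood high although no hCG had been given: Ereg (chosen after its values were seen) was at 14.67 against 3.88 to 10.75 in the other 5 arrays of 0 h, and Pgr at 10.44 against at most 4.71, while Snap25 (2.41) and Lepr (3.17) lay near the floor. The genes called in WT had gone a median share of 0.413 of the WT change in this array, where the Ex6DEL arrays of 4 h had 0.920 to 1.07. This argues against a 4 h sample in its place, but the array was part of the fit that called these genes. Genes in which it lay at the 4 h level gain error and tend not to be called, which lowers the share. RNA of a 4 h sample mixed in is argued against too, since 13 of the 27 immediate early genes lay above all 6 arrays of 4 h, against 0 to 2 in the other arrays of 0 h, and a mixture would lie between its parts. Stress during collection stays open, as the heat shock mean was 0.14 above the highest other array of 0 h, within their SD of 0.39. An early response to the animals' own LH, or collection at another time, may also account for it and was not tested.

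The 6 genes lower in Ex6DEL at 0 h shared a profile in which the 3 WT arrays of 0 h were raised and the 9 other arrays lay close together, within 0.00 for Hlcs to 0.39 for Ccdc8. A shift of dim probe sets in these 3 arrays was counted on the 26907 probe sets that stand for no tested gene. Of these, 8 had the 9 other arrays within 0.25 and all 3 of WT 0 h at least 0.3 above them, against 3, 2 and 7 for WT 4 h, Ex6DEL 0 h and Ex6DEL 4 h, and of the 18188 genes not called at 0 h 4 did so against 0, 0 and 1, so the shift stays open. Only Minar2 and Abraxas1 had other probe sets, so Ccdc8 and the remaining genes could not be checked in this way. These 3 other probe sets had a median difference of 0.043 at 0 h, where the 6 probe sets used had -0.92. The other probe sets are dim and may miss the measured transcript, so a true genotype difference in the level of the 6 transcripts stays open.

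In Ex6DEL 0 h replicate 1 the theca and stroma list stood at 10.12, above 7.01 to 7.90 in the other 5 arrays of 0 h, with Cyp17a1 at 15.14 against at most 11.59, Col1a2 at 15.20 against 12.98, Col3a1 at 15.00 against 13.13 and Dcn (chosen after its values were seen) at 13.94 against 10.68. Of 11 other stromal genes, which are in none of the lists, 8 lay above the other 5 arrays after quantile normalization, where those had 0 to 2 such genes, which is consistent with theca and stroma cells carried along during follicle puncture, although WT arrays of 0 h express 12 of the 15 list members above the median level of all genes. A stretched scale of this array is argued against, since after quantile normalization the list mean was still 1.35 above the highest other array of 0 h (SD 0.55). A lower share of granulosa cells stays open, since theca and stroma cells carried along would lower it too. The larger rise of the endothelial and leukocyte lists was 0.54, where the theca and stroma list rose by 2.61. Only 4 of the 14 endothelial and 7 of the 16 leukocyte members lay above the median level in WT 0 h, so these lists can move little. The preovulatory granulosa list was itself the highest of 0 h at 12.51, and after quantile normalization at 11.87 against at most 11.63. Whether the theca cells of these mice were more active was not tested.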

How the results depend on the processing

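The fits without both WT 0 h replicate 1 and Ex6DEL 0 h replicate 3 were chosen after the data were seen, and all others were planned. Where a result changed, the cause was not tested, except that fewer genes, fewer arrays or a stricter threshold change a count by construction. The WT response had 169 genes, and 271 with quantile normalization (142 shared), 369 with one median (154 shared), 525 of the genes above the median level, 2289 with array weights, 17 with only the groups compared, 17 at an adjusted p under 0.01, 320 without the 2 arrays and 573 without them above the median level. The Ex6DEL response had 394 genes, and 441 with quantile normalization (307 shared), 1334 above the median level, 10 with only the groups compared, 8 at an adjusted p under 0.01, 1293 without the 2 arrays and 2302 without them above the median level. At 0 h the genotypes differed in 6 genes, and in 1 with one median, 0 above the median level, 20 with array weights, 0 with only the groups compared, 10 with every probe set tested, 61 without the 2 arrays and 1 without them above the median level. At 4 h limma called 0 genes (294 at an unadjusted p under 0.05) and 3 with every probe set tested. The interaction had 2 genes, and 1 with quantile normalization, 1 with one median, 0 above the median level, 1 at an adjusted p under 0.01, 10 with every probe set tested, 28 without the 2 arrays and 0 without them above the median level. With the replicate number as a block the counts were 85, 92, 3, 0 and 1, in the order WT, Ex6DEL, 0 h, 4 h and interaction. Outside the Ex6DEL response at least 1 of the 3 pairs of each comparison correlated under 0.1 (0.180, 0.555 and -0.0449 at 0 h, 0.727, 0.372 and -0.0156 at 4 h, 0.0860, 0.236 and 0.0155 in WT). Of 6 arrays 4, 3 and 3 correlated best with their own number, so the number does not pair all arrays there. Single pairs, replicate 1 at 4 h (0.727) and replicate 2 at 0 h (0.555), lay above the highest Ex6DEL pair of 0.405. Whether a call lost there reflects other errors or weaker effects was not tested. The block ended 2 of the 8 list calls at 0 h, ovulatory and immediate early, and no other list call. Leaving out 1 array gave 50 to 344 genes for WT, 26 to 1256 for Ex6DEL, 4 to 49 at 0 h, 0 to 35 at 4 h and 2 to 23 for the interaction, each changed by the arrays named beside the counts above. The correlation of the responses was 0.850 with quantile normalization, 0.854 above the median level and 0.738 (without WT 4 h replicate 1) to 0.818 with 1 array left out. The Smarca1 difference of 0.04 at 0 h turned to -0.47 with quantile normalization, -0.35 with array weights and -0.14 without the 2 arrays, and ranged from -0.17 to 0.23 with 1 array left out. Its difference at 4 h of -0.04 turned to 0.14 with quantile normalization, 0.019 with one median and 0.038 with array weights (range -0.47 to 0.44), and its interaction of -0.08 to 0.60 with quantile normalization, 0.39 with array weights and 0.10 without the 2 arrays (range -0.51 to 0.40). Fgl2 ranged from -0.20 (without Ex6DEL 0 h replicate 1) to 2.16 at 0 h and from -1.36 to 0.86 (without WT 4 h replicate 1) at 4 h. Among members of lists that had not passed, Rbbp7 turned to -0.14 in WT with quantile normalization, and without the 2 arrays Sox17 to 2.47e-04 in WT, Epb42 to 0.01 and Krt18 to -0.092 in Ex6DEL. With 1 array left out the change ranged in WT from -3.72e-04 to 0.45 for Tie1, -0.086 to 2.47e-04 for Sox17 and -0.044 to 0.28 for Slc4a1. In Ex6DEL it ranged from -0.0029 to 0.42 for Emcn, -0.13 to 0.0051 for Epb42, -0.11 to 0.0098 for Rhag, -0.10 to 1.13 for Krt7 and -0.092 to 0.54 for Krt18. At 0 h the call of the ovulatory list was lost without the 2 arrays (mean 0.12, adjusted p = 0.976), as that of the steroid list was with quantile normalization (mean 0.12, adjusted p = 0.972), each with lower as the direction in camera. With 1 array left out the ovulatory mean ranged from -0.13 to 1.46, the immediate early mean from -0.48 to 1.54 and the theca and stroma mean from -0.090 to 1.42. The genes named by their change or p in a contrast, and the list members named for the WT and Ex6DEL responses, were followed under the alternatives. Other than Smarca1 and Fgl2 they gave 789 values on the same side and in the same direction, 80 newly passing and 51 no longer passing under the other settings, and 1906, 40 and 350 with 1 array left out. The 789 and 1906 include genes that had not passed to begin with, and only the 61 calls among them could be lost. In every fit without 1 array, 3 of 26 calls in WT and 4 of 29 in Ex6DEL passed. The same held for 3 of 5 at 0 h and the 1 of the interaction. All 61 calls kept their sign. List members named at 0 h, at 4 h and for the interaction were not followed. With fry 6 of the 12 lists called in WT stayed called (ovulatory, cumulus, steroid, cytokine, coagulation and luteal), 4 of 8 in Ex6DEL (ovulatory, cumulus, preovulatory and cytokine), and none of the 8 at 0 h, the 2 at 4 h and the 5 of the interaction. Signal over background limits these results, since 28.1% of the tested values lay within 0.1 of the floor.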

Other observations

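The splits of the arrays described at the end of this part were planned, and the genes and probe sets described first were chosen after their values had been seen.

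Star, which carries cholesterol into mitochondria at the start of steroid synthesis, differed widely between arrays before hCG. It had 6.37 in Ex6DEL 0 h replicate 1 against 13.44 and 14.20 in replicates 2 and 3, and 11.46, 12.40 and 8.22 in WT 0 h replicates 1, 2 and 3, while all 6 arrays of 4 h lay between 13.96 and 15.28. WT 0 h replicate 1 had raised levels of a few ovulatory genes as well. Its Ereg, a ligand of the EGF receptor, was at 10.75 against 3.88 and 4.06 in the other WT arrays of 0 h, and its nuclear receptor Nr4a1 at 12.74 against 8.89 and 8.80, while its Sult1e1 (2.29), Pgr (3.82) and Ptgs2 (5.33) lay far below the 4 h arrays. Among the probe sets without a single gene symbol 1 differed between genotypes at 0 h, 3 at 4 h and 1 in the interaction.

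Other splits of the same arrays gave fewer genes for the hCG responses. For WT the real split gave 169 genes and the highest of the others 2, for Ex6DEL 394 and 3, and at 0 h 6 and 3, so that in each of these 1 of the 10 splits, the real one, gave as many. For the hCG responses every other split mixes arrays of 0 h and 4 h on both sides. The hCG change then enters the error, so low counts there do not measure chance. At 4 h the real split gave 0 genes, so all 10 gave as many, and the highest other, WT replicate 1 with Ex6DEL replicates 1 and 3 against the rest, gave 22. It was picked as the highest of 9. On the first principal component its 3 arrays lay at -67.0, -66.2 and -63.2 and the other 3 at -40.7, -36.5 and -18.6, so the 4 h arrays have a structure along the axis that parts 0 h from 4 h. With 10 splits a share under 0.05 cannot be reached. For the interaction 25 of 100 drawn splits, the real one included, gave at least 2 genes and the highest other gave 65, so chance is not excluded as the source of its 2 genes.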
